A study of Homo sapiens with 6 samples.

How the data were processed

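Gene expression was measured in SKOV3 cells, an established human ovarian cancer cell line, after 11 days of culture in McCoy's 5A medium and 15% serum. Per the labels, the control cells grew on normal attachment plates (2D, n = 3) and the other cells on low-attachment plates in medium with 0.015% (w/v) FP001 (3D, n = 3). FP001 is a medium additive known here only by its code name. Total RNA was extracted on columns, and biotin-labelled material was prepared from 100 ng of total RNA for 1 array per sample. The design text states that each sample was collected 3 times, and nothing in the labels says whether the samples of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

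The deposited table holds log2 values for 53617 probe sets on 6 arrays. Per the submitters' processing notes they were made with RMA, which corrects background, equalises the distributions of the arrays and summarises each probe set. The software version, the probe grouping and any filters are not given in the sources used here. The log2 scale was inferred from the values, which ran from 0.30 to 13.87 with array medians of 4.30 to 4.37, and no gene had been centred. The probe annotation belongs to a Human Gene ST array, whereas the labels' protocol names a 3′ IVT labelling kit. This mismatch was left unresolved. RMA fold changes are compressed for dim probe sets, and levels of different probe sets cannot be set against each other. The table holds no detection calls, so no gene was called absent.

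Genes were named through the platform annotation used here, in which 16098 probe sets carried 1 symbol, 0 carried several and 37519 carried none. The gene identifiers of all 16098 named probe sets were found in a RefSeq gene table (assembly GRCh38.p14), used only for current symbols and gene types. Each gene was represented by the probe set with the highest mean over all arrays, which left 14884 genes, 11916 of them protein-coding and 779 with more than 1 probe set. Probe sets without a symbol entered no gene or list comparison and were tested only with all probe sets. The number of arrays limits the precision.

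The groups were compared with limma 3.58.1 (statmod 1.5.0) in R 4.3.3, fitting group alone to the log2 values, with moderated variances and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The larger changes were counted at an absolute log2 fold change of at least 1. Gene lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The camera test was repeated with an estimated correlation. Members were also counted with p-values adjusted over the list alone. The 28 lists were fixed before the data were examined and covered these themes: hypoxia-inducible genes, glycolytic enzymes, mitotic genes, DNA replication genes, cell cycle inhibitors and p53 targets, cholesterol biosynthesis and uptake, fatty acid synthesis, oxidative phosphorylation, fibrillar and basement membrane matrix, integrins and focal adhesion, YAP and TAZ targets, contractile actin cytoskeleton, epithelial markers, mesenchymal markers, interferon-stimulated genes, MHC class I antigen presentation, NF-kB cytokines and targets, ATF4 and unfolded protein response, cytosolic heat shock proteins, NRF2 targets, metallothioneins, MAPK feedback and target genes, lysosome and autophagy, BCL2 family, ovarian cancer stem cell markers, Notch and Wnt targets, and markers of leukocytes and of fibroblasts and endothelium.

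The genes to be named were also set by rule before the data were examined. They were the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, leaving out unnamed loci. In each list up to 4 members past the threshold with the largest absolute change were added. A further 12 genes were to be given whatever their result; 7 of them are reported and 5 are not analysed here. Members named in addition, to identify a small count, were chosen after their values were seen, as stated beside them.

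The alternatives were a repeated quantile normalization, centring on array medians, a filter on dim probe sets, the mean or the most variable probe set of a gene, all probe sets tested singly, a trended robust variance, the replicate number as a block, and a per-gene test with unequal variances and no shared variance. A test against a 1.2-fold limit, the directional fry test for lists and leaving out each array in turn were also run. Counts of list members without 3D replicate 1, and a scan of gene families, were added after the data had been seen. A comparison of RNA quality control probe sets had been planned and was not run, because the annotation used here does not name them.

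The fit was tested on simulated data for 14884 genes with 3 arrays per group. It recovered 22% of genes raised 1.5-fold, 72% of those raised 2-fold, 98% of those raised 4-fold and 100% of those lowered 4-fold. Of 151 calls, 5 were false (3.31%). The real comparison called 1488 genes, and the cutoff that the adjustment sets depends on how many genes change. The recovered shares therefore hold for the simulated setting only. A list shifted in the simulation was called, and 0 of the unshifted lists were called. The simulated noise was independent between genes, so it could not show false list calls that arise when members vary together. In the real data the estimated correlation was 0.94 for the mitotic list.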

Results

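Expression profiles of SKOV3 ovarian cancer cells were compared between attached (2D) culture and low-attachment (3D) culture with FP001, with 3 arrays per condition. The comparison asked how gene expression differs when the cells are grown by the 3D method for 11 days. Plate and additive changed together, so their effects cannot be separated in this design. Values are log2 RMA values, and changes are given as 3D minus 2D.

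The groups were well apart. The first principal component held 59.1% of the variance and separated 2D from 3D, and correlations across genes ran from 0.991 to 0.993 among 2D arrays and from 0.975 to 0.982 between groups. In the 3D group, replicates 2 and 3 correlated at 0.995, and 3D replicate 1 correlated with each at 0.988. On the next component, with 18.4% of the variance, 3D replicate 1 lay at -26.0 and the other 3D arrays at 9.39 and 10.1. Of 14884 genes, 1488 changed at an adjusted p under 0.05 (limma), 778 higher and 710 lower in 3D. Among these, 259 rose and 169 fell at least 2-fold, and 405 of these 428 genes are protein-coding. At an unadjusted p under 0.05 there were 3493 genes. The groups did not overlap for 4341 genes (29.2%, where chance gives 10%). Without 3D replicate 2 or 3D replicate 3 the changed genes numbered 795 and 775, without single 2D arrays 876 to 921, and without 3D replicate 1 1899. The per-gene test with unequal variances and no shared variance called 82.

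The largest rise belonged to the long non-coding RNA LINC01088, from 2.79 ± 0.19 to 7.53 ± 0.36 (SD, n = 3 per group), a log2 fold change of 4.74 ± 0.19 (SE, adjusted p = 3.72e-05). Its 2D level lay below the mean lower quartile of the arrays (2.93), and the mean of its 5 probe sets gave a change of 2.36. LUM, encoding the small leucine-rich proteoglycan lumican, rose from 6.08 ± 0.34 to 10.47 ± 0.08 (SD, n = 3), which is 21.0-fold (adjusted p = 3.58e-05). ENPP2, which encodes the lysophosphatidic acid-producing enzyme autotaxin, rose 18.8-fold, and the homeobox gene DLX3 rose 17.1-fold. The peptidase gene CPM rose 10.8-fold, TMT1B 10.6-fold, the cytokine gene IL33 10.6-fold, the secretory-epithelium gene AGR2 9.99-fold and SUSD2 9.92-fold. The basal keratin gene KRT5 rose by 3.22 ± 0.62 (SE, adjusted p = 0.0173), VSIG1 by 3.14 ± 0.46 and SYTL5 by 3.03 ± 0.21. KRT5 read 5.83 in 3D replicate 1 against 8.34 and 8.16 in the other 3D arrays, and its call was lost without 3D replicate 2 or 3 or any single 2D array (adjusted p up to 0.0708, without 2D replicate 3).

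GFRA1, encoding a receptor for glial cell line-derived neurotrophic factor, fell the most, from 9.77 ± 0.25 to 5.09 ± 0.51 (SD, n = 3), a log2 fold change of -4.68 ± 0.25 (SE, adjusted p = 8.45e-05). The proteoglycan gene SRGN fell 18.4-fold, from 9.51 ± 0.0048 to 5.31 ± 0.21 (SD). The kinase gene ALPK2 fell 12.9-fold, the matricellular gene THBS1 11.8-fold, the collagenase gene MMP13 9.42-fold and LRRN4 9.10-fold. Falls of 6.70-fold in AMTN, 6.43-fold in the carboxypeptidase gene CPA4, 6.25-fold in LINC03033 and 5.99-fold in the receptor tyrosine kinase gene AXL followed, and the polo-like kinase gene PLK2 gave a change of -2.58 ± 0.13 (SE). PSG1 fell by 3.35 to a 3D level of 1.81, under the lower quartile, and its near-identical paralogs make this value uncertain. All 3 arrays of one group lay above all 3 of the other for each of these genes, as the naming rule required.

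**Figure D1:**
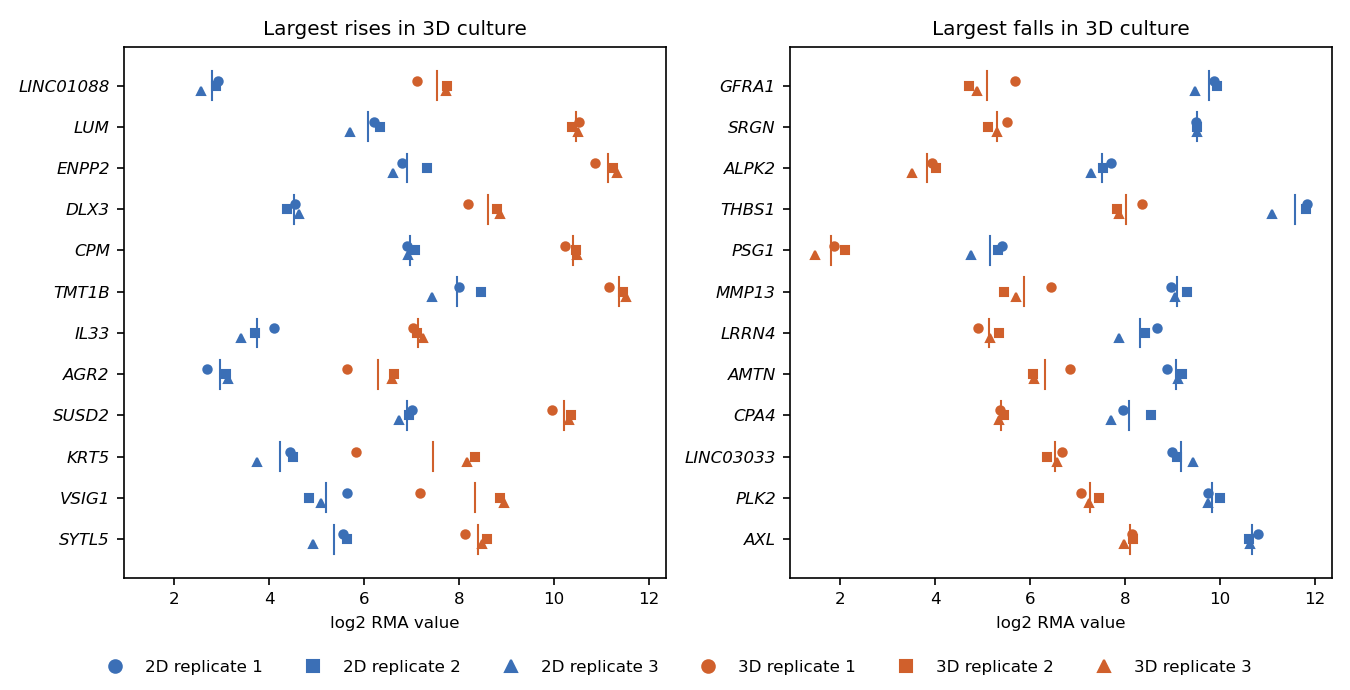
Log2 RMA values (horizontal axis) of the 12 genes with the largest rises (left) and the 12 with the largest falls (right), for 3 arrays of 2D culture (blue) and 3 of 3D culture (orange). Points are single arrays, with symbols for replicates 1 to 3, and short vertical lines are group means; KRT5 lies at 5.83 in 3D replicate 1 and at 8.34 and 8.16 in the other 3D arrays.

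Of 13 measured targets of YAP and TAZ, the transcriptional co-activators that respond to cell spreading, 9 fell, 1 rose and 3 did not pass. Adjusted over the list alone, 11 fell and 1 rose. The largest falls were those of AXL (-2.58 ± 0.10 SE, n = 3), AJUBA (-1.81 ± 0.13), ANKRD1 (-1.64 ± 0.27) and the matricellular gene CCN2 (-1.46 ± 0.26). The riser was IGFBP3 (0.50), named after its value was seen. The median change was -0.66 (camera adjusted p = 9.01e-08, and adjusted p = 0.0896 with an estimated correlation). Of 11 contractile actin cytoskeleton genes, 5 fell and 0 rose, with 6 falling when adjusted over the list alone. They were the myosin light chain kinase gene MYLK (-1.87 ± 0.09), TAGLN (-1.62 ± 0.14), TPM1 (-1.25 ± 0.17), CNN2 (-1.04 ± 0.11) and TPM4 (-0.37), the last named after its value was seen. The list's median was -0.34 (camera adjusted p = 0.000143, and adjusted p = 0.152 with an estimated correlation).

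Of 25 genes on the matrix list 6 were measured, without any collagen or laminin gene. Of these 6, 5 fell over all genes and adjusted over the list alone. Among them were THBS1 (-3.56 ± 0.23 SE, n = 3), the tenascin C gene TNC (-1.71 ± 0.32), the fibronectin gene FN1 (-1.38 ± 0.24) and the basement membrane gene NID1 (-0.53 ± 0.12). HSPG2 (-0.51), the other member that fell, was named after its value was seen. The median was -0.96 (camera adjusted p = 0.000143, and adjusted p = 0.28 with an estimated correlation). Of 25 genes on the integrin and focal adhesion list 8 were measured, and no integrin gene was among them. Of these 8, 3 fell, 0 rose and 5 did not pass, and 5 fell adjusted over the list alone. The focal adhesion gene TNS1 fell from 5.64 ± 0.04 to 4.64 ± 0.04 (SD, n = 3), and ZYX (-0.65 ± 0.11 SE) and TGFB1I1 (-0.60 ± 0.12) fell as well. The median was -0.36 (camera adjusted p = 0.00461, and adjusted p = 0.209 with an estimated correlation). Leaving out single arrays ended the calls of TNC (2D replicate 1 or 3 or 3D replicate 3, adjusted p up to 0.0606), FN1 (2D replicate 1, 0.0512) and ZYX (2D replicate 2 or 3, up to 0.0526). It also ended those of NID1 (any array except 3D replicate 1, adjusted p up to 0.131) and TGFB1I1 (2D or 3D replicate 2 or 3, up to 0.0812). CCN2 did not pass as the mean of its 2 probe sets (-1.14, adjusted p = 0.0536).

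Of 18 measured epithelial markers 9 rose, 2 fell and 7 did not pass, and 11 rose and 3 fell adjusted over the list alone. The cadherin genes CDH1 and CDH2, of the epithelial and mesenchymal lists, were not among the measured genes. Keratin 19 (KRT19) rose by 2.70 ± 0.24 (SE, n = 3), the adhesion molecule gene EPCAM by 1.76 ± 0.11, the epithelial splicing factor gene ESRP1 by 1.54 ± 0.28 and the tight junction gene TJP3 by 1.40 ± 0.12. The members that fell were KRT7 (-0.93) and TJP1 (-0.37), named after their values were seen. The median was 0.62 (camera adjusted p = 2.44e-05, and adjusted p = 0.209 with an estimated correlation). Of 10 mesenchymal markers 2 fell and 0 rose, with 4 falling adjusted over the list alone, and the list did not pass (median -0.26, camera adjusted p = 0.0881, and 0.283 with an estimated correlation), whereas fry called it (0.0157). Without 3D replicate 1, 4 members fell and 1 rose. The 2 that fell were FN1 and the repressor gene ZEB2 (-0.52 ± 0.11), and vimentin (VIM) gave -0.37 ± 0.09 at an adjusted p of 0.0501. VIM passed in several alternatives, the mean of its 3 probe sets among them (adjusted p = 0.0344). Calls that a single left-out array ended were ESRP1 (2D replicate 2 or 3D replicate 3, adjusted p up to 0.0539) and ZEB2 (any 2D array or 3D replicate 2, up to 0.106).

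Among 13 ovarian cancer stem cell markers, 4 rose and 1 fell, and the list did not pass (median 0.28, camera adjusted p = 0.0564). The counts were 4 and 2 adjusted over the list alone, and 3 and 2 without 3D replicate 1. EPCAM, the Wnt-associated receptor gene LGR5 (1.34 ± 0.21 SE, n = 3), CD44 (0.58 ± 0.14) and SOX9 (0.53, named after its value was seen) rose, whereas CD24 fell by 1.21 ± 0.10. Of 15 Notch and Wnt targets 1 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.06, camera adjusted p = 0.108, and 0.315 with an estimated correlation). These were the Wnt feedback genes AXIN2, which rose by 1.26 ± 0.19, and DKK1, which fell by 1.24 ± 0.25. CD44 lost its call without any array except 3D replicate 1 (adjusted p up to 0.121) and DKK1 without 2D replicate 1 or 2 or 3D replicate 3 (up to 0.0809). The stem cell list passed in 3 of the fits without 1 array (adjusted p = 0.0316 without 3D replicate 3, 0.0463 without 2D replicate 2 and 0.0468 without 2D replicate 1) and with fry (0.0253), but not with an estimated correlation over all arrays (0.283). Fry also called the Notch and Wnt list (adjusted p = 0.0332).

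**Figure D2:**
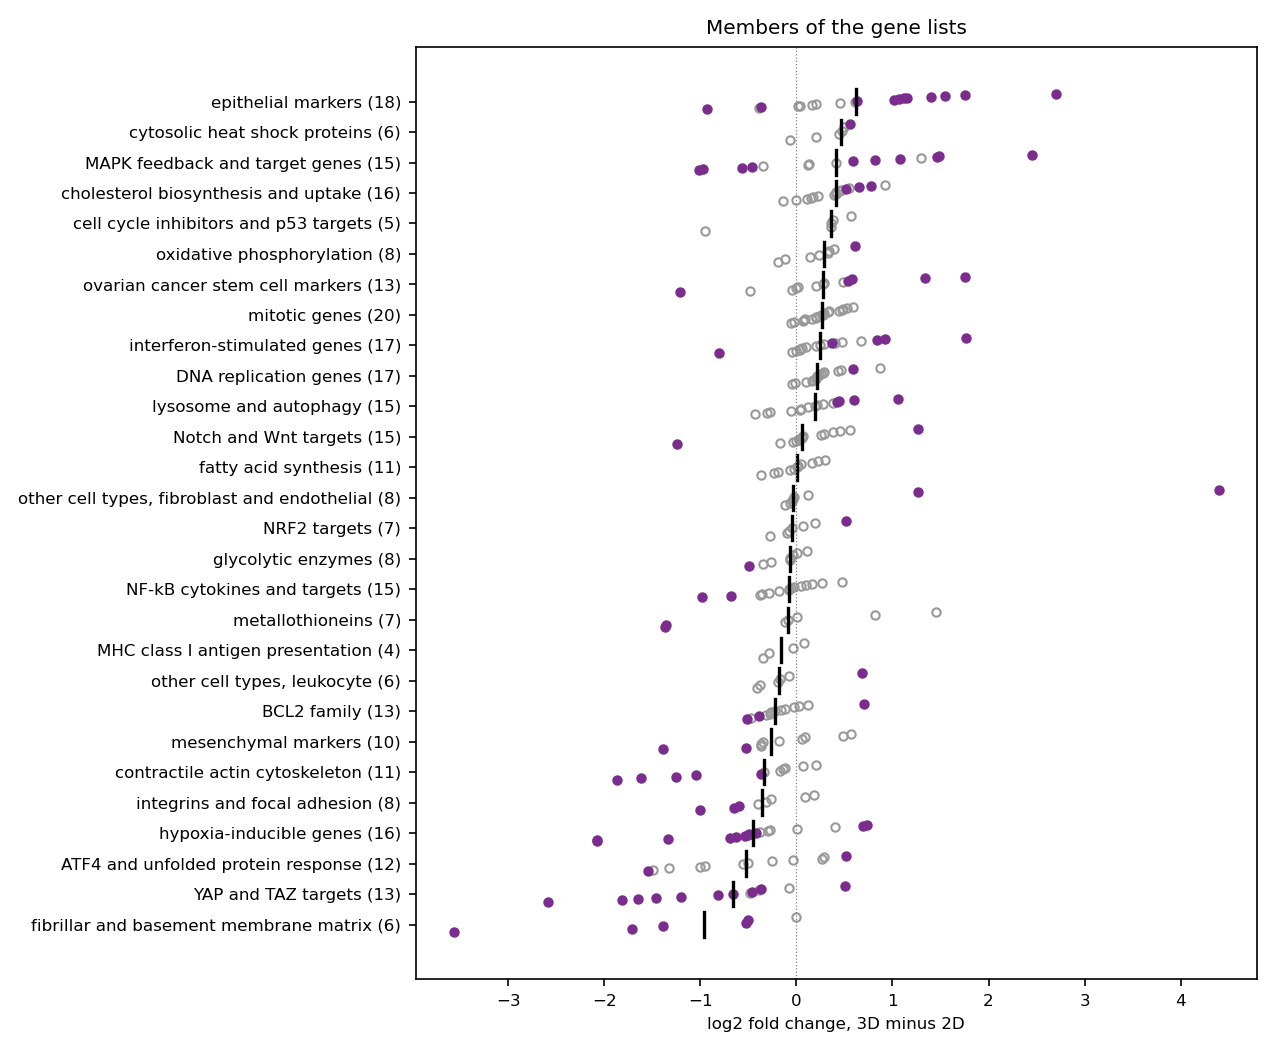
Log2 fold change of 3D minus 2D (horizontal axis) for the measured members of each gene list, with the number of members in parentheses. Filled points passed an adjusted p under 0.05, open points did not, and black lines are list medians; the lowest median is -0.96 for matrix genes and the highest 0.62 for epithelial markers.

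Of 26 hypoxia-inducible genes on the list 16 were measured, and CA9, PDK1 and SLC2A1 were among those not measured. Of the 16 measured genes 9 fell, 2 rose and 5 did not pass, and 12 fell and 3 rose adjusted over the list alone. The angiogenic factor gene VEGFA (-2.08 ± 0.25 SE, n = 3), the mTOR regulator gene DDIT4 (-2.07 ± 0.37) and the mitophagy gene BNIP3 (-1.34 ± 0.10) fell. ANGPTL4 rose by 0.73 ± 0.13, as did EGLN3 (0.70), named after its value was seen. The median was -0.46 (camera adjusted p = 0.000143, and adjusted p = 0.209 with an estimated correlation). Array means of the list, relative to each gene's mean, were 0.20 to 0.32 in 2D and -0.12 in 3D replicate 1 against -0.34 and -0.28 in the other 3D arrays. Without 3D replicate 1, 7 members fell and 1 rose. Of 8 glycolytic enzymes 1 fell, hexokinase HK2 (-0.49 ± 0.11), 2 fell adjusted over the list alone, and GAPDH gave -0.06 ± 0.09 (adjusted p = 0.764). That list did not pass (median -0.06, camera adjusted p = 0.137, and 0.315 with an estimated correlation), whereas fry called it (0.0274), and 0 members fell without 3D replicate 1. Calls that a single left-out array ended were DDIT4 (2D or 3D replicate 3, adjusted p up to 0.0526), ANGPTL4 (2D replicate 2 or 3D replicate 2 or 3, up to 0.0522) and HK2 (any array except 2D replicate 2, up to 0.114).

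Of 16 cholesterol biosynthesis and uptake genes 3 rose, 0 fell and 13 did not pass, and 6 rose adjusted over the list alone. They were DHCR7, the enzyme of the last step of cholesterol synthesis (0.78 ± 0.19 SE, n = 3), the sterol-responsive transcription factor gene SREBF2 (0.65 ± 0.14) and NSDHL (0.52 ± 0.10). HMGCS1 gave 0.55 ± 0.21 (adjusted p = 0.162). The median was 0.41 (camera adjusted p = 0.000173, and adjusted p = 0.374 with an estimated correlation), and fry did not call the list (adjusted p = 0.108). The list mean was -0.08 in 3D replicate 1 and 0.37 and 0.28 in the other 3D arrays, against -0.02, -0.18 and -0.37 in the 2D arrays. 3D replicate 1 thus lay below 2D replicate 1. Without 3D replicate 1, 8 members rose. DHCR7, SREBF2 and NSDHL each lost the call without 2D or 3D replicate 2 or 3, with an adjusted p of up to 0.146, 0.108 and 0.0684. Of 11 fatty acid synthesis genes 0 passed by either adjustment (limma), and 1 higher and 2 lower members had an unadjusted p under 0.05 (median 0.01 with a mean of -0.01, camera adjusted p = 0.939). Of 26 oxidative phosphorylation genes 8 were measured, without any NDUF, SDH or ATP synthase gene. Of these 8, 1 rose by both adjustments, the cytochrome c oxidase subunit gene COX5B (0.61 ± 0.13, adjusted p up to 0.0973 without 2D or 3D replicate 2 or 3). That list did not pass (median 0.29, camera adjusted p = 0.0574, and 0.28 with an estimated correlation), but it passed without 2D replicate 1 (adjusted p = 0.0468), after a repeated quantile normalization (0.0477) and with fry (0.0157), and 3 members rose without 3D replicate 1.

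Of the proliferation genes, 1 passed singly. The proliferation marker MKI67 gave 0.07 ± 0.25 (SE, n = 3, adjusted p = 0.905). Of 20 mitotic genes 0 passed by either adjustment (limma), and 2 higher members had an unadjusted p under 0.05, with a median of 0.27 (camera adjusted p = 0.0228, and adjusted p = 0.592 with an estimated correlation). Their array means were 0.28, -0.13 and -0.55 in the 2D arrays and -0.08, 0.30 and 0.18 in the 3D arrays, and the list did not pass without 2D replicate 3 (adjusted p = 0.544) or 3D replicate 2 (adjusted p = 0.115), or with fry (adjusted p = 0.441). Of 17 DNA replication genes 1 rose, the flap endonuclease gene FEN1 (0.59 ± 0.15, adjusted p up to 0.16 without 2D or 3D replicate 2 or 3), and 0 passed adjusted over the list alone (5 higher members had an unadjusted p under 0.05). That list had a median of 0.22 (camera adjusted p = 0.00423, and adjusted p = 0.473 with an estimated correlation), and it did not pass without 3D replicate 2 (adjusted p = 0.0615) or with fry (adjusted p = 0.217). Array means of the replication list were 0.04, -0.21 and -0.24 in the 2D arrays and -0.12, 0.31 and 0.22 in the 3D arrays, so the groups overlapped. Without 3D replicate 1, 3 replication genes rose. Of 17 cell cycle inhibitors and p53 targets 5 were measured, without any CDKN gene or MDM2. Of these 5, 0 passed over all genes (limma). Adjusted over the list alone, and at an unadjusted p under 0.05, 4 rose and 1 fell. The list median was 0.36 (camera adjusted p = 0.0828, and 0.323 with an estimated correlation). Without 2D replicate 2 this list passed at an adjusted p of 0.0491, as it did with fry (0.0467), and without 3D replicate 1 1 member rose and 1 fell.

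**Figure D3:**
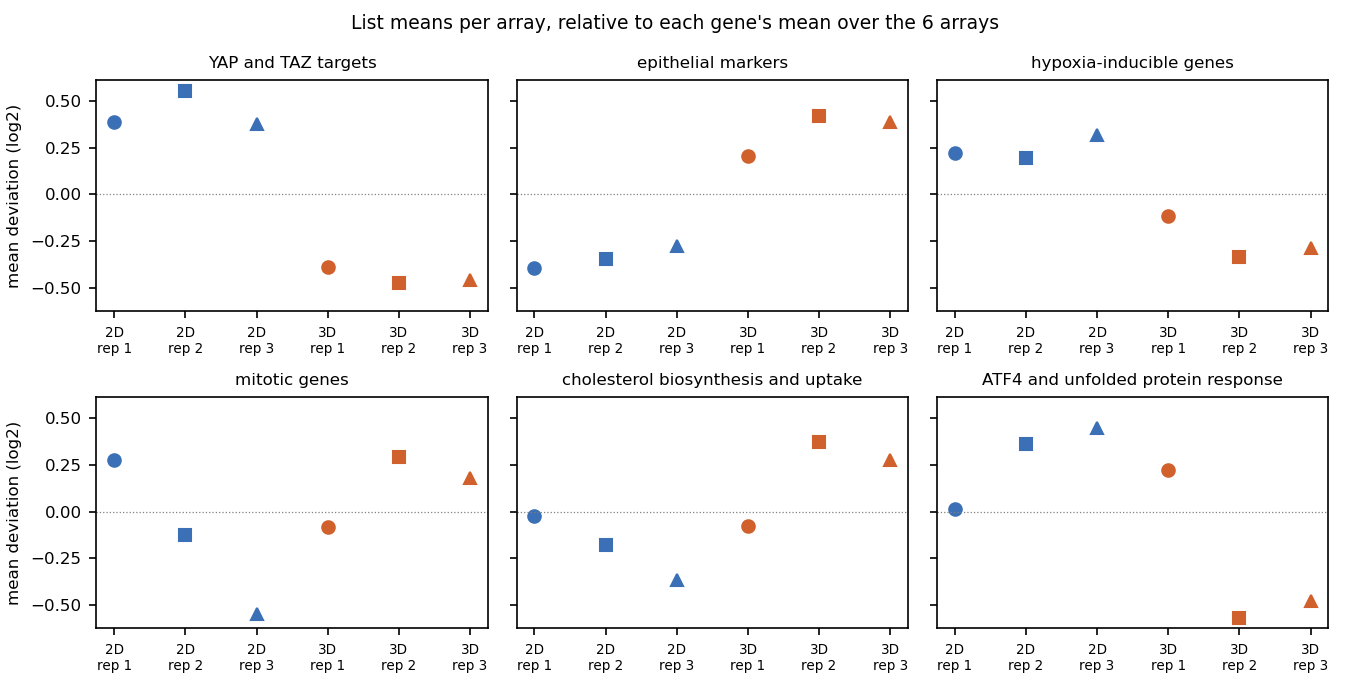
Mean deviation (log2, vertical axis) of the measured members of 6 gene lists from each gene's mean over the 6 arrays, per array, for 2D (blue) and 3D (orange) culture, with symbols for replicates 1 to 3. The mitotic list spans 0.28 to -0.55 within the 2D arrays, and 3D replicate 1 lies at 0.23 for the ATF4 list against -0.57 and -0.48 in the other 3D arrays.

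Of 15 measured MAPK feedback and target genes 6 rose, 4 fell and 5 did not pass, and 8 rose and 5 fell adjusted over the list alone. The ERK phosphatase gene DUSP6 rose by 2.46 ± 0.15 (SE, n = 3), the Sprouty genes SPRY4 and SPRY2 by 1.48 ± 0.11 and 1.47 ± 0.12, and the ETS factor gene ETV1 by 1.08 ± 0.16. The members that fell were the transcription factor genes FOSL1 (-1.02) and MYC (-0.97) and the ephrin receptor genes EPHA4 (-0.57) and EPHA2 (-0.46), named after their values were seen. The median was 0.42 (camera adjusted p = 0.0464, and adjusted p = 0.374 with an estimated correlation). The list did not pass without 2D replicate 1 (0.118), 3D replicate 1 (0.0863) or 3D replicate 2 (0.0521). It also did not pass with the filter on dim probe sets (0.0694), the mean of all probe sets of a gene (0.0706) or the most variable probe set (0.0929).

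Of 17 interferon-stimulated genes 4 rose and 1 fell by both adjustments. IFI44L rose by 1.76 ± 0.16 (SE, n = 3) from a 2D level of 2.86, under the lower quartile, the virus-tethering gene BST2 by 0.93 ± 0.15 and USP18 by 0.84 ± 0.18. RIGI (0.37) also rose and was named after its value was seen, and XAF1 fell by 0.80 ± 0.19. The median was 0.24 (camera adjusted p = 0.00425, and adjusted p = 0.28 with an estimated correlation), and the list did not pass with the filter on dim probe sets (adjusted p = 0.0533). Leaving out 3D replicate 1 gave 5 risen and 0 fallen members. Of 4 MHC class I genes, too few for the list test, 0 passed over all genes, and 1 fell adjusted over the list alone and at an unadjusted p under 0.05 (limma, median -0.16). Of 15 NF-kB cytokines and targets 2 fell, the chemokine gene CXCL8 (-0.98 ± 0.15) and the adhesion gene ICAM1 (-0.68 ± 0.14), and the list did not pass (1 rose and 2 fell adjusted over the list alone, and the same counts without 3D replicate 1; median -0.08, camera adjusted p = 0.215). Calls that a single left-out array ended were USP18 (2D replicate 1 or 3 or 3D replicate 2 or 3, adjusted p up to 0.0947), XAF1 (any array except 3D replicate 3, up to 0.123) and ICAM1 (2D or 3D replicate 2 or 3, up to 0.097).

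Stress-related lists gave few calls. Of 12 ATF4 and unfolded protein response genes 1 fell, the serine synthesis gene PHGDH (-1.54 ± 0.35 SE, n = 3), and 1 rose, SDF2L1 (0.52 ± 0.12), with 5 falling and 2 rising adjusted over the list alone (median -0.53, camera adjusted p = 0.0926). Without 3D replicate 1, 7 fell and 1 rose, and the list passed at the preset correlation (adjusted p = 0.00251). It also passed without 2D replicate 1 (adjusted p = 0.0468), and over all arrays it did not pass with an estimated correlation (0.552) or with fry (0.396). Of 6 cytosolic heat shock genes 1 rose, HSPH1 (0.55 ± 0.14), and 4 rose adjusted over the list alone. Their median was 0.46 (camera adjusted p = 0.0228, and adjusted p = 0.323 with an estimated correlation), and the list did not pass without 3D replicate 2 (0.0521) or with fry (0.0608). Leaving out 3D replicate 1 gave 3 risen heat shock genes. Of 7 NRF2 targets 1 rose by both adjustments, the pentose phosphate gene PGD (0.51 ± 0.09; list median -0.04 with a mean of 0.04, camera adjusted p = 0.569). Of 7 metallothionein genes 2 fell, MT1X (-1.37 ± 0.22) and MT2A (-1.36 ± 0.18), with 2 falling and 2 rising adjusted over the list alone, and also without 3D replicate 1 (median -0.09, camera adjusted p = 0.459, and 0.538 with an estimated correlation). Fry called this list (adjusted p = 0.0423). Metallothionein genes resemble each other in sequence, so their single values are uncertain. PHGDH, SDF2L1 and HSPH1 each lost the call without any array except 3D replicate 1, with an adjusted p of up to 0.109, 0.108 and 0.165, and PGD without 3D replicate 2 or 3 (up to 0.0588).

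Of 15 lysosome and autophagy genes 4 rose, and 6 rose and 3 fell adjusted over the list alone. The cathepsin genes CTSS, CTSL and CTSD rose by 1.06 ± 0.11, 0.44 ± 0.09 and 0.43 ± 0.09 (SE, n = 3), and the sialidase gene NEU1 by 0.60 ± 0.12. The median was 0.20 (camera adjusted p = 0.0231, and adjusted p = 0.315 with an estimated correlation), and the list did not pass without 2D replicate 1 (0.0573) or 3D replicate 1 (0.079, with 4 risen and 1 fallen members). Of 13 BCL2 family genes the pro-apoptotic BCL2L11 rose by 0.70 ± 0.11, and the anti-apoptotic BCL2L1 (-0.51 ± 0.11) and the pro-apoptotic BAD (-0.38 ± 0.09) fell. Adjusted over the list alone, 1 rose and 3 fell (median -0.23, camera adjusted p = 0.0574, and 0.28 with an estimated correlation), and without 3D replicate 1 this list passed (adjusted p = 0.0343, with 1 risen and 3 fallen members). It also passed with a trended and robust variance (0.0449) and with fry (0.0157). CTSL and CTSD each lost the call without any array except 3D replicate 1 (adjusted p up to 0.0992 and 0.114), BAD without any array (up to 0.148) and NEU1 without 2D replicate 1 or 3 or 3D replicate 2 or 3 (up to 0.0719). BCL2L1 lost it without any 2D array or 3D replicate 3 (adjusted p up to 0.0964).

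Markers of cell types outside the line were also listed. Of 6 leukocyte markers 1 rose by both adjustments, the lysosomal glycoprotein gene CD68 (0.68 ± 0.11 SE, n = 3; list median -0.18, camera adjusted p = 0.444), and 1 rose and 1 fell without 3D replicate 1. Of 8 fibroblast and endothelial markers 2 rose by both adjustments, LUM and the adhesion gene PECAM1 (1.27 ± 0.14). That list had a median of -0.03 and a mean of 0.69 and did not pass (camera adjusted p = 0.0881, and 0.283 with an estimated correlation), but it passed without 2D replicate 3 (adjusted p = 0.0438) and with fry (0.00429).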

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

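The tests on 3D replicate 1, the hypoxia list and the mitotic list were chosen after the results were seen; the count of splits was planned. Of the 37519 probe sets without a symbol, which enter no gene or list comparison, 200 were at least 2-fold higher in 3D at an adjusted p under 0.05 (limma) and 150 at least 2-fold lower. They were singled out as a signal in data outside the gene comparison.

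The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1488 changed genes, 428 of them at least 2-fold, and 13 called lists, and the highest of the other splits gave 0, 0 and 6. In each case 1 split, the real one, reached its value. Every other split mixes 2D and 3D arrays on both sides, which puts the group difference into the spread within each side. Low counts of changed genes were thus built into those splits, and the contrast with the real split cannot judge chance.

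3D replicate 1 reached 81.6% (95% bootstrap interval 77.7 to 83.0) of the log2 shift of the genes changed at least 2-fold without it. The bootstrap resampled genes, so the intervals given here cover the spread among genes and not that between arrays. 3D replicates 2 and 3 reached 105% each, measured against means that hold 3D replicate 1. An admixture of 2D RNA would need the same share from both directions, but risen genes needed 34.2% (28.8 to 37.8) and fallen genes 7.30% (5.00 to 10.6), which argues against it as the whole cause. Compressed signal on that array could not be judged in this way. A level-dependent correction left the share at 80.7% (78.2 to 83.0), but it moved risen and fallen genes of equal level in the same direction. Their shares then shift oppositely, so the pooled share could hardly change. In unchanged genes the deviation of that array changed by -0.034 per log2 unit of level, a slight compression. A difference in the state of that culture, or in handling before hybridisation, may account for the pattern and stays open. The design names no difference among the 3D samples, so no biological explanation was tested.

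Of 26 hypoxia-inducible genes on the list 16 were measured, of which 9 fell, 2 rose and 5 did not pass. Their median was -0.46 (camera adjusted p = 0.000143, and adjusted p = 0.209 with an estimated correlation). A level-dependent trend between the groups is argued against, because none of 10000 level-matched random lists had a median as low (share 0.0001, the smallest these draws can give). The ATF4-responsive members VEGFA and DDIT4 do not carry the call at the preset correlation alone: without them the other 14 members had a median of -0.40 (camera adjusted p = 0.00213, and adjusted p = 0.209 with an estimated correlation). The culture condition itself may lower the members that fell, as a hypothesis, and the plate and FP001 cannot be separated. Cell density and medium age at harvest were not given in the labels and stay open.

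The mean of the mitotic genes ranged over 0.83 (log2) within the 2D arrays and 0.38 within the 3D arrays, against 0.26 between the group means. A level-dependent scale difference between arrays is argued against, since the widest range in 10000 level-matched random lists over the 2D arrays was 0.24 (share 0.0001, the smallest these draws can give). Differences in the share of dividing cells between the samples may account for it, which was not tested. The labels name no difference within a group, so no biological explanation was tested.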

How the results depend on the processing

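All alternatives were planned except the counts without 3D replicate 1 and the family scan. No named gene and no list reversed in any of them. Of 82 named genes past the threshold, 51 kept their call in every alternative other than the per-gene test with unequal variances, and 16 in that one too. Centring on array medians ended the calls of FEN1, DHCR7, HSPH1 and BAD. Across the fits without 1 array, changed genes ranged from 775 to 1899, at least 2-fold changes from 388 to 507 and called lists from 9 to 15. With the replicate number as a block 760 genes changed, 751 of them shared with the 1488, and the stem cell list passed (camera adjusted p = 0.0401). Same-numbered arrays of the groups had deviation correlations of -0.28, -0.06 and -0.18, which give no sign of pairing by number. Deviations were taken from each group's own mean, which constrains such correlations, so they cannot exclude a pairing. With unequal variances per gene 82 genes changed, 56 of them at least 2-fold. Testing all probe sets singly gave 1284 changes, 748 of them at least 2-fold, a larger set that holds unnamed probe sets. Camera with an estimated inter-gene correlation called 0 lists against 13 with the preset one, while fry called 18. Fry asks whether members change at all, and camera whether they change more than other genes, so their counts are not directly comparable. With the estimated correlation the lowest camera adjusted p was 0.0896, and 5 lists had an unadjusted p under 0.05. The estimates for the YAP and TAZ list (-0.007) and the contractile list (-0.023) lay under the preset 0.01. A higher correlation among members therefore does not account for the loss of those calls. The same setting was used for all lists, so the p-values given with it do not measure the effect of correlation alone. Of the 13 lists, 6 kept their call in every alternative but the estimated correlation. These were the hypoxia, matrix (no collagen or laminin gene measured), focal adhesion (no integrin gene measured), YAP and TAZ, contractile and epithelial lists. The cause of the other losses was not tested. The remaining alternatives gave 1393 to 1931 changed genes. The planned comparison of RNA quality control probe sets was not run, since the annotation used here does not name them. Signal near background limits the fold changes of dim genes: 73 of the 428 had a lower group mean under the median probe set.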

Other observations

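Beyond the genes named by rule, the genes given here were picked from the next-ranked changes after their values were seen. GREB1, an oestrogen-responsive gene, rose by 2.90 ± 0.13 (SE, n = 3), the neuroendocrine granule gene CHGA by 2.32 ± 0.15, the epithelial transcription factor gene SPDEF by 2.24 ± 0.17 and the interferon-inducible GTPase gene GBP5 by 2.29 ± 0.14. EPYC, a proteoglycan gene of the same chromosomal cluster as LUM, rose by 2.74 ± 0.13. Among the falls were the collagenase gene MMP1 (-2.51 ± 0.13), the lysyl oxidase-like gene LOXL2 (-2.12 ± 0.09), the growth factor gene NRG1 (-2.09 ± 0.12) and the matrix glycoprotein gene EFEMP1 (-2.10 ± 0.14). Each of these 9 genes had an adjusted p under 0.05 (limma).

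A scan of 230 groups of symbols with a shared stem and at least 8 measured members, added after the data had been seen, called 2 groups at the preset correlation. Of 10 DOCK genes 5 fell and 0 rose, with a group median of -0.48 (camera adjusted p = 4.34e-05, and adjusted p = 0.993 with an estimated correlation). They were DOCK4 (-1.63 ± 0.11 SE, n = 3), DOCK2 (-1.38 ± 0.21), DOCK10 (-1.07 ± 0.13), DOCK11 (-0.77 ± 0.10) and DOCK1 (-0.60 ± 0.09). In the other called group, PSG, 5 members fell and 0 rose (camera adjusted p = 0.00107, and adjusted p = 0.993 with an estimated correlation). That group held an antisense RNA and near-identical paralogs and is not described further.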
